A study of Mus musculus with 6 samples.

How the data were processed

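Immune cells from mouse tumours were profiled by droplet single-cell RNA sequencing with the 10x Genomics 5' kit and its feature barcode kit. Hashtag antibodies tied each cell to a mouse, and 138 further antibodies, 3 of them isotype controls, counted surface proteins on the same cells. The tumours came from a mixture of B16 melanoma cells and B78H1 cells; the sample titles write B7H1. After 3 weeks mice received cyclophosphamide, and the next day Trp1 cells, read here as T cells against the melanocyte antigen TRP1, with an antibody to OX40, a costimulatory receptor of T cells (aOX40), or with IgG. Tumour suspensions were made after 10 days. Untreated mice were a separate cohort implanted a week later. How the immune cells were enriched is not given in the sources used here.

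Per the labels, the authors processed the reads with Cell Ranger against mm10 and worked with Seurat 3.2.3; a Cell Ranger version is not given in the sources used here. The deposited matrices hold counts, as UMIs per gene and cell and as antibody tags per antibody and cell, with no normalization. The deposited annotation gives other, text fields for each cell (its library, hashtag, cluster name and cell label), and UMI counts per cell. It also gives the percent of UMIs from mitochondrial genes, which matched the matrix to within 5.33e-15. All 11548 deposited cells had a hashtag, at least 501 UMIs and at most 9.67% mitochondrial UMIs, so the authors had filtered them. How doublets were removed is not given in the sources used here, and no doublet test was run. The list of hashtag barcodes (not_used, as it holds no measurement) was not analysed here, and a Seurat object that the labels mention was not used here.

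Cells were grouped by deposited cluster name: 6 of neutrophils, 9 of monocytes, 1 of macrophages, 1 of dendritic cells and 1 of basophils. Each cluster was checked against fixed marker genes. A cluster failed where its leading genes held more markers of another class than of its own. Monocytes.1, Monocytes.5 and Monocytes.8 failed, so monocyte and macrophage clusters were compared by their own names. No neutrophil cluster failed, but only Neutrophils.3 (3 markers) and Neutrophils.4 (2) were led by neutrophil markers. The other neutrophil clusters were led by 0 markers of any class, so the check does not back their names. Leading genes of a cluster are the 10 with the highest log2 ratio of its CPM (counts scaled to a common total) to that of all other cells, with 10 CPM added to both. A mouse is a library and hashtag. The series states 5 mice per condition, but the IgG library held cells of 4 hashtags, so 14 mice were compared.

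For genes, UMIs of neutrophils were summed per mouse, leaving out 1 untreated mouse with fewer than 10 neutrophils, which gave 4 untreated, 4 IgG and 5 aOX40 mice. The sums held 14406 to 30319 UMIs in untreated, 749674 to 2306697 in IgG and 1312493 to 2605886 in aOX40 mice. edgeR 4.0.16 (R 4.3.3) fitted all groups together with TMM normalization, its filter on low counts and the quasi-likelihood test, with Benjamini-Hochberg adjusted p and a threshold of 0.05. CPM in the text are TMM-normalised means over mice with SD, and log2 fold changes carry the SE of the fit. Where all untreated mice had 0 counts, the fold is given against a floor of 3 counts over the group, 32.5 CPM, and covers counting error only. Antibody counts of neutrophils went through the same test over 138 proteins. Of 27 gene lists fixed beforehand, the 21 with at least 3 measured members were tested with camera (limma 3.58.1) at a correlation of 0.01 and, beside it, with an estimated correlation; fry was run as well. Shares of cells per mouse were compared by two-sided exact permutation tests, 39 in all, with Benjamini-Hochberg adjustment; with these group sizes the smallest p is 0.00794. Shares rest on mice with at least 50 cells in all. No minimum was set for percents of cells other than neutrophils.

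Genes named in the text came from a rule made before the data were examined. It takes the 10 largest rises and 10 largest falls among genes past the threshold whose mice did not overlap between groups, without predicted genes and receptor segments. It adds up to 4 members of each list with the smallest p and 9 fixed genes (Nos2, Tnf, Il1b, Cd274, Cxcl10, Isg15, Itgam, Cd14 and Arg1). The design, the lists and most alternatives were also fixed before the data were examined. Some lists share genes, so their results are not independent. All neutrophil markers are in the list of mature circulating neutrophils. The class I and interferon gamma lists share Tap1, Psmb8, Psmb9, Psmb10 and Nlrc5. Positions come from the reference annotation of GRCm38.p6, in which 14196 of 15342 gene symbols were found.

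On counts with changes added to 200 of 5836 genes, the test called 43% of 2-fold and 92% of 4-fold changes for aOX40 against IgG, with 13 false calls. For IgG against untreated these were 8% and 33%, with 10 false calls beside 8 and 33 right ones, and for aOX40 against untreated 4% and 16%, with 1 false call, since each untreated mouse held at most 23 neutrophils. On protein counts 90% or more of 2-fold changes were called in each comparison.

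Alternatives were size factors of the RLE type, DESeq2 1.42.0, no filter on low counts, only the groups compared, mice with at least 30 cells, thinning, hashtag as a block, leaving out the 5% of cells with the most UMIs, and leaving out each mouse. Added after the data were seen were scaling by total counts, neutrophils by the label of each cell, leaving out each neutrophil cluster, tests within clusters Neutrophils, Neutrophils.3 and Neutrophils.4, thinning of the treated mice alone, and leaving out the 2 treated mice richest in monocytes. The fit within Neutrophils.3 took mice with at least 10 of its cells, so untreated mouse 3 and IgG mouse 5 dropped out. Its untreated mice held at most 15 cells each, so a call lost there can reflect few cells. Each condition was 1 library, so library and condition cannot be told apart, and p-values cover the spread between mice only. Gene tests in monocytes and macrophages, dendritic cells, CD4 and CD8 T cells and NK cells were not run, nor was the test of neutrophils against macrophages. They needed 3 mice with at least 10 cells in each group: 1 IgG and 2 aOX40 mice had 10 cells of clusters named after monocytes or macrophages, 0 treated mice had 10 dendritic cells, and 0 treated cells had a T or NK label. The share of T cells with the transferred receptor was not computed for the same reason. Shares of neutrophil clusters among a mouse's neutrophils were compared by 3 exact permutation tests, for Neutrophils, Neutrophils.2 and Neutrophils.3 between aOX40 and IgG mice. They were not tested for the other clusters, or against untreated mice, where each cluster's leading genes include genes called between the groups.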

Results

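The data hold RNA and surface protein counts of 11548 immune cells from tumours of 14 mice. The untreated library held 6192 cells of 5 mice and 58699967 UMIs, with 10892525 to 12318759 UMIs per mouse. The IgG library, from mice given cyclophosphamide, Trp1 T cells and IgG, held 1660 cells of 4 mice and 6642064 UMIs (796452 to 2388088 per mouse). The aOX40 library, from mice given the same with the OX40 antibody, held 3696 cells of 5 mice and 12378787 UMIs (1589627 to 3384893 per mouse).

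Tumours of treated mice yielded almost only neutrophils, which were few in untreated mice. Neutrophils, short-lived phagocytes of the innate immune system, made up 1.33% ± 0.511 (SD, n = 5) of the cells of an untreated mouse, 94.9% ± 6.95 (SD, n = 4) of an IgG mouse and 94.1% ± 7.77 (SD, n = 5) of an aOX40 mouse. Dendritic cells, which carry antigen to T cells, were 3.10% ± 1.39 of untreated cells; 0 of 1660 IgG cells and 2 of 3696 aOX40 cells were in their cluster. The largest cluster named after monocytes in untreated mice was Monocytes.3, led by Dmkn, Vcan and Chil3, at 24.3% ± 5.50; it held 0.175% ± 0.351 of IgG and 0.574% ± 0.983 of aOX40 cells.

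In exact permutation tests neutrophils were 93.6 percentage points higher in IgG and 92.7 points higher in aOX40 than in untreated mice, above every untreated mouse in all 4 IgG and all 5 aOX40 mice. Both had an exact permutation p = 0.00794, the smallest these tests can give, and adjusted p = 0.0141 over 39 tests. Between aOX40 and IgG mice the neutrophil share differed by -0.871 points (exact permutation p = 0.825, adjusted p = 0.92), less than the spread between mice. As percent of all cells, each cluster named after monocytes or macrophages and the dendritic cells were lower in both treated groups. Their adjusted p was 0.0141, save 0.0269 for Monocytes.5 in IgG mice and 0.0495 for Monocytes.2 in both groups. As percent of cells other than neutrophils the direction turned for Monocytes.2, which was 68.3 points higher in IgG and 36.6 points higher in aOX40 than in untreated mice (both adjusted p = 0.019). Those percents rest on few cells. Clusters named after monocytes or macrophages held 5 to 43 cells per IgG mouse and 5 to 103 per aOX40 mouse. In IgG mouse 5 all 5 such cells were of Monocytes.2. On that scale Macrophages, Monocytes, Monocytes.1 and Monocytes.6 in IgG mice and Monocytes, Monocytes.4 and dendritic cells in aOX40 mice lost their calls (adjusted p from 0.0752 to 0.865). Basophils, which carry Mcpt8, Il4 and Fcer1a, were 0.778% ± 0.46 (n = 5) of aOX40 cells against 0.0161% ± 0.0361 (n = 5) of untreated cells (exact permutation p = 0.00794, adjusted p = 0.0141). Against IgG mice, at 0.0877% ± 0.175 (n = 4), the exact permutation test of basophils gave p = 0.0397 and adjusted p = 0.0595, which missed the threshold. Shares sum to 100%, and each depends on how its library was enriched and loaded.

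**Figure D1:**
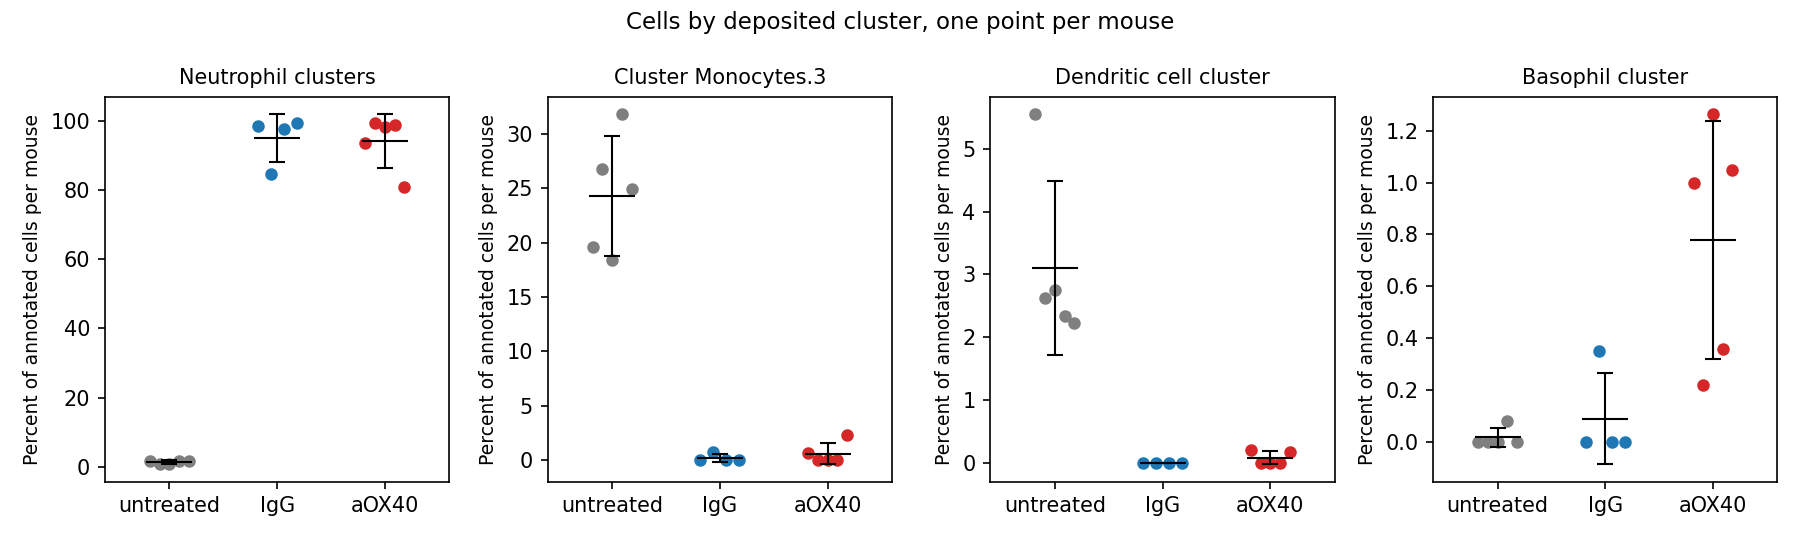
Percent of the annotated cells of each mouse in the neutrophil clusters, cluster Monocytes.3, the dendritic cells and the basophils (points, 1 per mouse; horizontal line and bar, mean and SD), by group. Neutrophils lay between 84.6% and 99.2% in IgG mice and between 0.679% and 1.77% in untreated mice.

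The neutrophils fell into 6 deposited clusters with distinct leading genes. Neutrophils.4 was led by G0s2, Cxcr2, Cxcl3 and Cxcl2, receptors and chemokines of neutrophil recruitment among them, and held 1773 of 3519 aOX40, 349 of 1597 IgG and 11 of 83 untreated neutrophils. The cluster named Neutrophils was led by Atp6v0d2, Gadd45b and Hilpda, the last a hypoxia-induced lipid droplet protein; it held 1036 aOX40, 855 IgG and 15 untreated cells. Neutrophils.2, with the secondary granule genes Ltf, Camp and Ngp in front, held 117, 225 and 0 cells. Neutrophils.3, with Mmp9, Retnlg and Csf3r of circulating neutrophils, held 117, 57 and 56 cells, most of the untreated neutrophils. Neutrophils.5, led by Spp1 and Csf3, held 469, 32 and 1. Neutrophils.1, led by Nos2, Saa3 and Arg1, held 7, 79 and 0 cells; of the 79, 50 were of IgG mouse 2, 23 of IgG mouse 5, and 2 and 4 of IgG mice 3 and 4. As percent of a mouse's neutrophils, Neutrophils.2 was lower in aOX40 (4.02 ± 3.38, n = 5) than in IgG mice (13.9 ± 1.85, n = 4; exact permutation p = 0.0159, adjusted p = 0.0357 over 3 tests), in all 5 against all 4. Cluster Neutrophils was lower too (31.6 ± 11.3 against 51.8 ± 6.16; exact permutation p = 0.0238, adjusted p = 0.0357), and Neutrophils.3 did not pass the test (3.68 ± 2.70 against 5.11 ± 4.89; exact permutation p = 0.611, adjusted p = 0.611). Without any 1 treated mouse but IgG mouse 4 or aOX40 mouse 5 both calls were lost (adjusted p up to 0.107 for Neutrophils and 0.0857 for Neutrophils.2). With fewer mice the test allows fewer permutations and its smallest p is larger. A lost call therefore need not mean that the difference rested on that mouse. Both clusters stayed lower in aOX40 mice with any 1 treated mouse left out. The other counts are a makeup and were not tested.

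Comparing aOX40 with IgG mice asks what the OX40 antibody added in neutrophils when both groups had cyclophosphamide and T cells. Neutrophils of aOX40 mice held less RNA of Saa3 and Nos2. Saa3, an acute phase protein, was at 19.7 ± 28.3 CPM (SD, n = 5) against 378 ± 167 (SD, n = 4), and Nos2, the inducible nitric oxide synthase, at 90.5 ± 64.8 against 558 ± 280. They held more of Hbegf, a growth factor of the EGF family, at 203 ± 154 against 25.1 ± 29.1 CPM, and of Olr1, a scavenger receptor for oxidised lipoprotein, at 274 ± 176 against 52.0 ± 14.6. In edgeR 359 of 5836 genes changed, 159 higher and 200 lower in aOX40 mice, and 260 of them (93 higher, 167 lower) were called in the same direction under 4 scalings or tools (93 higher and 223 lower with total counts). Groups did not overlap for 9.54% of genes, where chance gives 1.59%.

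The log2 fold change was -4.40 ± 0.67 (SE) for Saa3 (adjusted p = 0.00182) and -2.64 ± 0.46 for Nos2 (adjusted p = 0.0043). It was 3.07 ± 0.64 for Hbegf (adjusted p = 0.0109) and 2.41 ± 0.38 for Olr1 (adjusted p = 0.00167). Each had all 5 aOX40 mice on 1 side of all 4 IgG mice, which the rule for the largest rises and falls requires. Each kept its call with any mouse left out. The other largest rises were Ffar2, a receptor for short-chain fatty acids, Cass4, Myo1d, Chac1, Hgf, Map3k14, Prr3 and Tec, from 1.70 to 2.36. Among the other largest falls were Cfb, a complement factor (-4.04), Sdc3 (-3.73), the chemokine Cxcl16 (-2.73), Smpdl3b, Rasa4, F11r and Tbc1d9 (-2.40). Prr3 lost its call in each fit with 1 mouse left out that could test it (adjusted p up to 0.146); without IgG mouse 5 or 2 Myo1d (adjusted p up to 0.0581), Chac1 (0.0559), Hgf (0.107), Tec (0.0658), Rasa4 (0.0639) and Tbc1d9 (0.0831) did. Nos2 and Saa3 lead cluster Neutrophils.1, which held 79 IgG and 7 aOX40 cells with a median of 14526.5 UMIs, more than any other neutrophil cluster, and 24 of its 86 cells labelled macrophage or monocyte. Whether they were doublets was not tested. Without that cluster Saa3 fell by 4.24 (adjusted p = 0.00196) and Nos2 by 2.03 (adjusted p = 0.0165); Cfb (-2.77, adjusted p = 0.0747) and Rasa4 (-1.76, adjusted p = 0.143) lost their calls, and Sdc3, Cxcl16 and Prr3 were too low to test. Within single clusters some calls were kept. Olr1 (2.49, adjusted p = 0.0118), Ffar2 (2.80, adjusted p = 0.0118), Cass4 (1.61, adjusted p = 0.0203), Map3k14 (1.69, adjusted p = 0.0397) and Tec (1.16, adjusted p = 0.0421) kept theirs within cluster Neutrophils. Hbegf (2.96, adjusted p = 0.0238) and Ffar2 (2.36, adjusted p = 0.0231) did within Neutrophils.4. Other calls were lost. Within cluster Neutrophils Nos2 was at -0.91 (adjusted p = 0.0697), Hbegf at 2.80 (adjusted p = 0.0546) and Myo1d at 1.36 (adjusted p = 0.0918). Within Neutrophils.4, which Olr1 and Cass4 lead, Nos2 was at -1.37 (adjusted p = 0.227), Olr1 at 1.34 (adjusted p = 0.0751), Cass4 at 0.84 (adjusted p = 0.285), Map3k14 at 0.87 (adjusted p = 0.285), Myo1d at 0.92 (adjusted p = 0.304), Chac1 at 1.06 (adjusted p = 0.244) and Tec at 1.17 (adjusted p = 0.146). Hgf leads the basophil cluster, of which the aOX40 library held 27 cells and the IgG library 1. The genes lie on chromosome 7 (Saa3, 46711998 to 46719615), 11 (Nos2, 78920787 to 78960226), 18 (Hbegf, 36504927 to 36515805) and 6 (Olr1, 129479150 to 129507350) of GRCm38.p6.

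Some antigen presentation genes fell in aOX40 neutrophils. Of 19 genes of MHC class I presentation 3 fell (5 adjusted over the list alone): the peptide transporter gene Tap2 (-0.89, adjusted p = 0.0253) and the loading chaperones Tapbp (-0.95, adjusted p = 0.0301) and Tapbpl (-1.01, adjusted p = 0.0312). Each of the 3 lost its call without IgG mouse 2 or 5 or aOX40 mouse 2 or 3, and Tapbp also without aOX40 mouse 1, with adjusted p up to 0.152, 0.164 and 0.199. Of 7 class II genes 1 fell (5 adjusted over the list alone), H2-Ab1 (-1.57, adjusted p = 0.0348; called in 7 of 13 fits with 1 mouse left out, up to 0.161 without IgG mouse 2); without Neutrophils.1 it was at -0.61 (adjusted p = 0.552) and within cluster Neutrophils at 0.16 (adjusted p = 0.875). Of 9 nitric oxide and NADPH oxidase genes 2 fell (2 adjusted over the list alone), Nos2 and Ass1, the latter supplying arginine (-4.10 ± 0.83, adjusted p = 0.0119; 0.0759 in DESeq2). Without Neutrophils.1 Ass1 was too low to test. Of 23 interferon gamma response genes edgeR called 0 (0 adjusted over the list alone; 7 lower at unadjusted p under 0.05, 1 lower in DESeq2), and of 26 interferon alpha/beta response genes 0 by each of these counts. As sets against other genes, class I (camera adjusted p = 0.00189), class II (0.00189), interferon gamma (0.00218) and nitric oxide genes (0.0252) were lower. Each had adjusted p = 0.569 with an estimated correlation. At the fixed correlation camera called 9 of 21 lists here and a median of 7 over other splits of these mice. A call in camera alone is therefore weak evidence. The direction of the class II set turned within cluster Neutrophils (median 0.63, adjusted p = 0.162). That of the class I (median 0.11, adjusted p = 0.798), interferon gamma (0.17, adjusted p = 0.571) and nitric oxide sets (0.07, adjusted p = 0.798) turned within Neutrophils.3. In camera the class I set stayed lower within Neutrophils (median -0.45, adjusted p = 0.000116) and Neutrophils.4 (-0.37, adjusted p = 0.00297). So did the interferon gamma set (-0.48, adjusted p = 0.000194 and -0.44, adjusted p = 0.000576). With an estimated correlation both sets had adjusted p = 0.434 within Neutrophils and 0.479 within Neutrophils.4. The nitric oxide set also lost its call within Neutrophils (adjusted p = 0.26) and Neutrophils.4 (adjusted p = 0.0859), and the class II set within Neutrophils.4 (adjusted p = 0.145). The 9 listed macrophage markers were lower alongside these sets, at 131 CPM in aOX40 against 327 in IgG neutrophils.

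Among 25 NF-kB and TNF targets 1 rose and 2 fell (4 and 4 adjusted over the list alone). The set did not pass the test over all neutrophils (median 0.33, camera adjusted p = 0.35) and was lower within Neutrophils.4 (median -0.41, camera adjusted p = 1.28e-07; adjusted p = 0.479 with an estimated correlation). Nfkb1, which encodes the p105 precursor of NF-kB, rose (1.20 ± 0.26, adjusted p = 0.0126; 0.0827 without IgG mouse 5), while Sod2, the mitochondrial superoxide dismutase, fell (-1.07, adjusted p = 0.0312) and so did Relb (-0.89, adjusted p = 0.0393); both lost their calls without IgG mouse 2 or 5 or aOX40 mouse 3, with adjusted p up to 0.161 and 0.168, and Relb was called in 6 of 13 fits with 1 mouse left out. Of 20 genes of tumour-adapted neutrophils 2 rose (2 higher, 1 lower adjusted over the list alone): the chemokine receptor Cxcr4 (1.14, adjusted p = 0.0199; 0.108 without IgG mouse 5, 0.0831 without IgG mouse 2) and Spp1, a leading gene of Neutrophils.5 (1.16, adjusted p = 0.0489; called in 2 of 13 fits with 1 mouse left out, up to 0.152; -0.68, adjusted p = 0.261 within Neutrophils.4). Of 16 genes of mature circulating neutrophils Cxcr2, the receptor for neutrophil chemokines, rose (0.85, adjusted p = 0.045; called in 2 of 13 such fits, up to 0.185; 4 higher adjusted over the list alone); it leads Neutrophils.4, and was at 0.03 (adjusted p = 0.969) within that cluster. As a set these genes were higher (camera adjusted p = 0.0497; adjusted p = 0.734 with an estimated correlation). Of 10 granule genes of immature neutrophils 4 were higher and 1 lower at unadjusted p under 0.05 in edgeR. As a set they did not pass the test (median 0.58, camera adjusted p = 0.322). Past the threshold 1 fell (1 adjusted over the list alone), the collagenase Mmp8 (-0.94, adjusted p = 0.0473, called in 6 of 13 fits with 1 mouse left out, up to 0.157). Of 21 adhesion and activation receptors Cd69, also a leading gene of basophils, rose (0.99, adjusted p = 0.0442; called in 2 of 13 such fits, up to 0.191; -0.13, adjusted p = 0.915 within Neutrophils.4; 2 higher and 2 lower adjusted over the list alone).

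Of 10 genes of proinflammatory macrophages Nos2, the costimulatory ligand gene Cd86 (-1.55, adjusted p = 0.0103) and Cd38 (-2.21, adjusted p = 0.0296) fell (3 higher and 3 lower adjusted over the list alone). Cd86 lost its call without IgG mouse 2 (adjusted p = 0.0676), and Cd38 without IgG mouse 2 or 5 or aOX40 mouse 3 (up to 0.138). Without Neutrophils.1 Cd86 was at -0.92 (adjusted p = 0.0655) and Cd38 at -1.07 (adjusted p = 0.249). Of 4 macrophage markers Csf1r fell (-1.29, adjusted p = 0.0362; -0.47, adjusted p = 0.496 without Neutrophils.1; called in 5 of 13 fits with 1 mouse left out, up to 0.17; 1 adjusted over the list alone), and the 4 were lower as a set (camera adjusted p = 0.0497; adjusted p = 0.569 with an estimated correlation). All 9 listed macrophage markers summed to 131 CPM in aOX40 and 327 in IgG neutrophils, and 2608 in untreated cells of clusters named after monocytes or macrophages. Of 19 dissociation and stress genes Fosb rose (1.37, adjusted p = 0.0152; up to 0.0666 without IgG mouse 2 or 5; 1 higher and 1 lower adjusted over the list alone). That set was higher over all neutrophils (camera adjusted p = 0.0412; adjusted p = 0.569 with an estimated correlation) but lower within Neutrophils.4 (median -0.37, camera adjusted p = 0.00194; adjusted p = 0.479 with an estimated correlation). Neutrophil markers (camera adjusted p = 0.0415) and proliferation genes (0.0497) were higher as sets, both with adjusted p = 0.569 with an estimated correlation. All 8 neutrophil markers are also in the list of mature circulating neutrophils, so the rise of that list is not separate evidence. Of 24 hypoxia and glycolysis genes edgeR called 0 (0 adjusted over the list alone; 1 higher and 3 lower at unadjusted p under 0.05, 1 lower in DESeq2). The cytokine genes Tnf (-0.19, adjusted p = 0.713) and Il1b (0.82, adjusted p = 0.0962) and the checkpoint ligand gene Cd274 (-0.10, adjusted p = 0.904) did not pass the test.

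The count of 359 genes rested on single mice: it was 71 without IgG mouse 2, 62 without IgG mouse 5, 106 without aOX40 mouse 3, 206 without aOX40 mouse 4 and 732 without aOX40 mouse 5. It was 150 within cluster Neutrophils, 41 within Neutrophils.4, 80 without Neutrophils.4 and 937 without IgG mouse 3 and aOX40 mouse 5, the richest in monocytes. Of the called list members named above that could be tested within Neutrophils or Neutrophils.4, Tapbp (-1.05, adjusted p = 0.0118) and Sod2 (-1.10, adjusted p = 0.049) kept their calls within Neutrophils. All others, and these 2 within Neutrophils.4, did not (adjusted p from 0.0529 to 0.969).

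**Figure D2:**
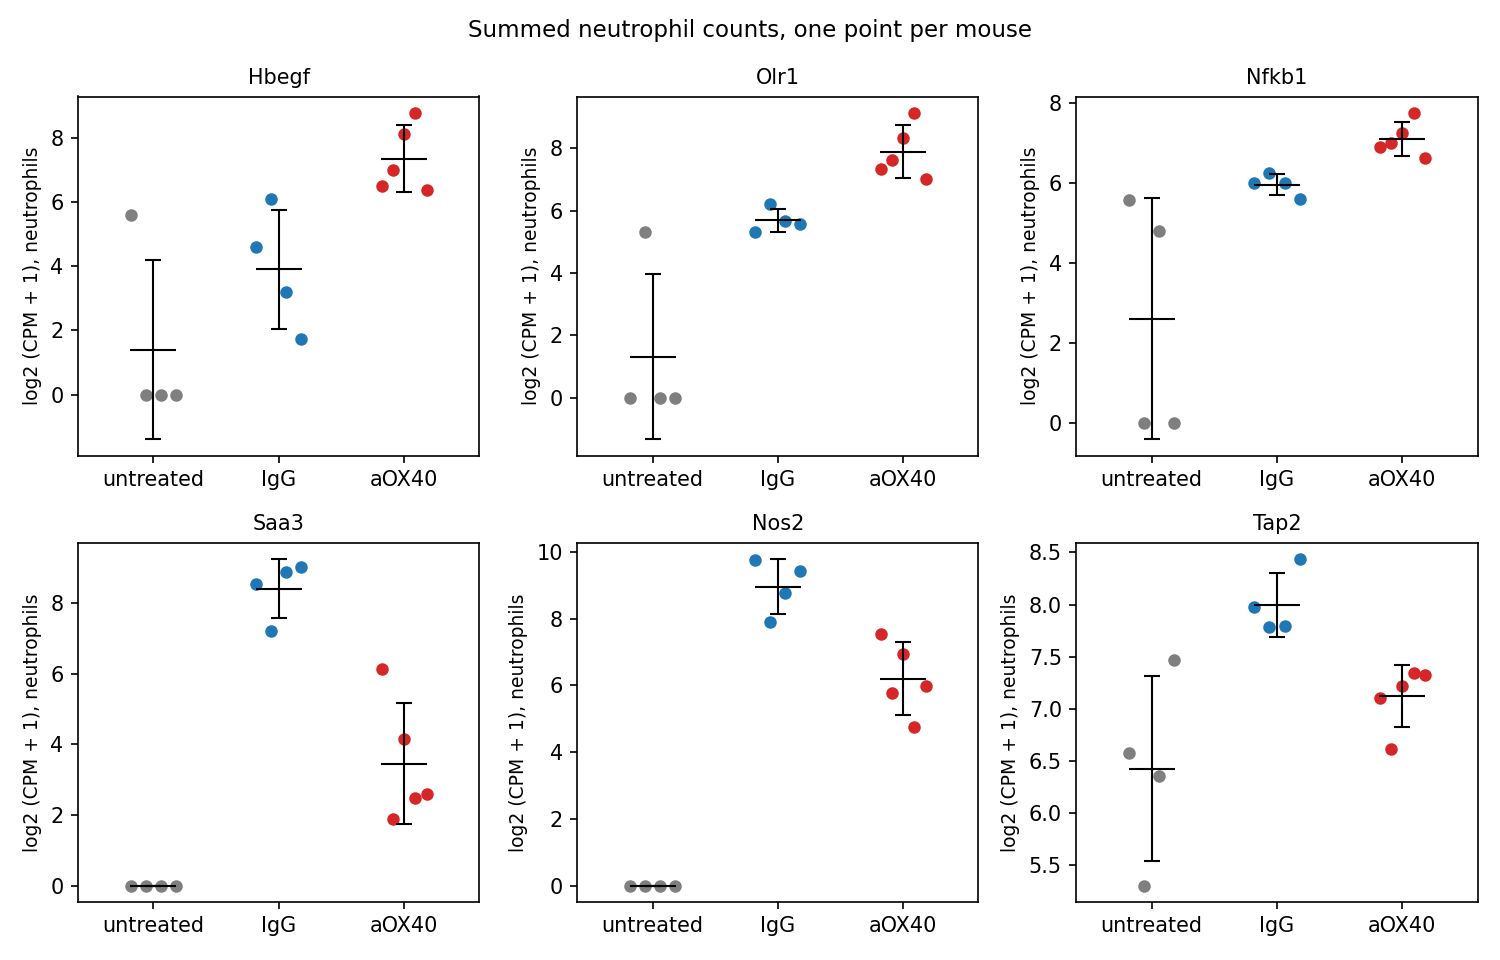
Summed neutrophil counts of 6 genes per mouse as log2 of CPM plus 1 (points, 1 per mouse; horizontal line and bar, mean and SD of the log2 values), by group. Saa3 and Nos2 had 0 counts in all 4 untreated mice, and 378 and 558 CPM on average in IgG mice.

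Surface proteins of the same neutrophils showed less CD11b and more Ly-6G in aOX40 than in IgG mice. No protein test was run within a cluster, and Neutrophils.4 held 1773 of 3519 aOX40 but 349 of 1597 IgG neutrophils. A different mix of clusters therefore cannot be told apart from a change within them. CD11b, the integrin chain that neutrophils use to adhere, was at 6978 ± 1015 antibody CPM (SD, n = 5) against 16414 ± 4870 (SD, n = 4), a log2 fold change of -1.23 ± 0.16 (SE) with adjusted p = 0.000324. Its RNA, Itgam, was at 0.19 ± 0.20 (adjusted p = 0.605); the difference between protein and RNA was not tested. Ly-6G, the classical mouse neutrophil marker, rose by 1.11 ± 0.21 (adjusted p = 0.00613), the antibody to Ly-6G/Ly-6C by 1.84 ± 0.30 (adjusted p = 0.00217), Ly-6C by 0.95 (adjusted p = 0.00792) and CD24 by 1.16 (adjusted p = 0.0082). These 5 kept their calls with any mouse left out. Ly-6G stood at 1946, 2994, 3372 and 2032 antibody CPM in IgG mice 2, 3, 4 and 5. The highest isotype control of that group was at 1948 CPM, so the size of its rise is not well resolved. In aOX40 mice Ly-6G stood at 4077 CPM or more, above their highest isotype control (2269 CPM). The RNA of Ly-6G, Ly6g, went the other way, at 106 CPM of pooled counts in aOX40 and 151 in IgG neutrophils, and edgeR did not call it. Untreated mice had more Ly-6G protein than either group, at 10120 antibody CPM or more, against 7564 or less in treated mice. CD301b (0.40, adjusted p = 0.0394) was the only other of 138 proteins past the threshold in edgeR; it lost its call with total count scaling (adjusted p = 0.0865) and in 7 of 13 fits with 1 mouse left out. CD14 (0.12, adjusted p = 0.936), PD-L1 (-0.09, adjusted p = 0.936) and OX-40 (-0.03, adjusted p = 0.936) did not pass the test.

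Comparing IgG with untreated mice asks how neutrophils differed after cyclophosphamide, T cells and IgG, with a week between the implantations. Neutrophils of IgG mice held more RNA of Cd274, H2-K1 and Slc2a1, called under all 4 scalings or tools. Cd274, which encodes the checkpoint ligand PD-L1, was at 2261 ± 427 CPM (SD, n = 4) against 284 ± 148 (SD, n = 4), and H2-K1, a class I heavy chain, at 3329 ± 398 against 548 ± 228. Slc2a1, the glucose transporter GLUT1, was at 720 ± 67.2 against 90.3 ± 53.1. Nos2 (558 ± 280 CPM), the granule gene Ngp (3100 ± 2513) and the interferon-induced GTPase gene Gbp4 (295 ± 85.7) had 0 untreated counts, so they were at least 17.2-fold, 66.4-fold and 8.63-fold higher.

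In edgeR 728 of 5836 genes changed, 661 higher and 67 lower in IgG mice. Groups did not overlap for 30.7% of genes, against 2.86% by chance among mice of like depth. Untreated sums were far shallower, so a low gene can read 0 in each untreated mouse and more in each IgG mouse. The 2.86% is therefore not the chance rate here. The direction rested on scaling: the median log2 fold change of all genes was 0.71 with TMM, 0.30 with RLE size factors and -0.19 with total counts, so changes are relative to it. Genes called higher and lower were 287 and 136 with RLE size factors, 317 and 249 in DESeq2 and 131 and 339 with total counts; 198 genes, 131 higher and 67 lower, were called in the same direction under these 4 scalings or tools. The count was 425 without untreated mouse 4 and 476 without untreated mouse 3, and within cluster Neutrophils.3, which holds most untreated neutrophils, 2 of 667 genes were called in edgeR. That fit lacked untreated mouse 3 and IgG mouse 5 and had at most 15 cells per untreated mouse. A call lost in it therefore does not show the absence of a change.

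Of 24 hypoxia and glycolysis genes 21 rose (22 adjusted over the list alone), 11 under all 4 scalings, among them Slc2a1 (2.92 ± 0.38, adjusted p = 0.000127), Gapdh (2.58) and Aldoa (2.31). The set was higher (median 2.16, camera adjusted p = 1.59e-32; adjusted p = 0.0324 with an estimated correlation) but lost its call within Neutrophils.3 (median 0.51, adjusted p = 0.202). Of 19 class I presentation genes 12 rose (16 adjusted over the list alone), 6 under all 4 scalings, with H2-K1 (2.58 ± 0.29, adjusted p = 3.08e-05) and B2m (1.81). Of 23 interferon gamma response genes 11 rose (16 adjusted over the list alone), 3 under all 4, with Cd274 (3.00 ± 0.41, adjusted p = 0.000157) and the transcription factor gene Irf1 (2.29). Of 20 tumour-adapted genes 10 rose (15 adjusted over the list alone), 5 under all 4, with the protease gene Ctsb (2.29) and the haem oxygenase gene Hmox1 (2.27; -0.13, adjusted p = 0.962 within Neutrophils.3). This set was higher too (median 1.61, camera adjusted p = 1.69e-12; adjusted p = 0.0324 with an estimated correlation), and less so within Neutrophils.3 (median 0.73, adjusted p = 0.03). Of 10 granule genes 7 rose (7 adjusted over the list alone), 4 under all 4, with Lcn2, an iron-sequestering protein (3.24 ± 0.43, adjusted p = 0.000151). Of 25 NF-kB and TNF targets 13 rose (13 adjusted over the list alone) but 1, Sod2 (2.84), under all 4. The class I, interferon gamma, granule and NF-kB sets were higher in camera (adjusted p from 7.28e-17 to 7.41e-09), with adjusted p = 0.1 for class I and 0.116 for the others with an estimated correlation. Within Neutrophils.3 these 4 kept their calls in camera, with medians of 1.66, 1.16, 2.21 and 0.54 against 2.04, 2.08, 4.30 and 1.22 over all neutrophils. Of genes, H2-K1 kept its call there (1.80, adjusted p = 0.0224), while Cd274 (adjusted p = 0.0501), B2m (0.143), Irf1 (0.218), Ctsb (0.295), Gapdh (0.365), Lcn2 (0.365) and Aldoa (0.608) did not.

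Of 21 adhesion and activation receptors 11 rose (12 adjusted over the list alone), and Cd14, the co-receptor for lipopolysaccharide, did so under all 4 scalings (2.16 ± 0.33, adjusted p = 0.000414). Of 19 dissociation and stress genes 8 rose (11 adjusted over the list alone), with Jun (2.26) and Hspa1a (3.80) under all 4; tissue handling is known to induce them. Of 26 interferon alpha/beta response genes 8 rose (8 adjusted over the list alone) and 0 under all 4 (3 in DESeq2, 10 at unadjusted p under 0.05). Among the largest falls were Mvb12b (-3.74 ± 0.61, adjusted p = 0.00064), which kept its call with any mouse left out, and Scnn1a, a leading gene of Neutrophils.3 (-2.53, adjusted p = 0.00458; 0.0531 without untreated mouse 4; -0.48, adjusted p = 0.684 within that cluster). The other 8 of the 10 largest falls rested on 6 to 13 untreated counts and each lost its call without 1 or more untreated mice, with adjusted p up to 0.284 for Kif23. The adhesion set (camera adjusted p = 1.57e-06) and the stress set (6.22e-07) were higher, both with adjusted p = 0.116 with an estimated correlation. Within Neutrophils.3 the adhesion set (median 0.26 against 1.06, adjusted p = 0.363), the interferon alpha/beta set (0.25 against 0.76, adjusted p = 0.405), Cd14 (1.76, adjusted p = 0.0501) and Jun (1.25, adjusted p = 0.533) lost their calls. Camera also called class II genes (adjusted p = 0.0149; adjusted p = 0.415 with an estimated correlation), mature circulating neutrophil genes (0.0149; adjusted p = 0.513 with an estimated correlation), interferon alpha/beta response genes (0.00651; adjusted p = 0.557 with an estimated correlation) and proinflammatory macrophage genes (0.0283; adjusted p = 0.205 with an estimated correlation) higher. On pooled counts scaled by their totals, with genes at 0 untreated counts at their bound, the medians of the interferon alpha/beta (-0.35) and proinflammatory macrophage genes (-0.06) were below 0 but above that of all genes (-0.46).

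Comparing aOX40 with untreated mice asks how neutrophils differed after the full treatment. Neutrophils of aOX40 mice held more RNA of Cxcl2, a chemokine that recruits neutrophils, at 60711 ± 22236 CPM (SD, n = 5) against 12210 ± 7680 (SD, n = 4), and of Cd14, at 5521 ± 1942 against 818 ± 324. Cd274 was at 2113 ± 955 against 284 ± 148 CPM and Spp1, osteopontin, at 2782 ± 1293 against 447 ± 246. Ngp, Camp and the stefin gene Stfa2 had 0 untreated counts and were at least 81.3-fold, 65.6-fold and 19.0-fold higher; Stfa2 has close paralogs, so its reads are hard to place. Nos2 (90.5 ± 64.8 CPM, 0 untreated counts) was at least 1.97-fold higher and did not pass the test (adjusted p = 0.077).

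In edgeR 818 of 5836 genes changed, 763 higher and 55 lower in aOX40 mice. Groups did not overlap for 28.9% of genes, against 1.59% by chance among mice of like depth. The shallow untreated sums can part low genes here too, so 1.59% is not the chance rate. The median log2 fold change of all genes was 0.70 with TMM, 0.22 with RLE size factors and -0.35 with total counts. Genes called higher and lower were 293 and 131 with RLE size factors, 336 and 256 in DESeq2 and 125 and 388 with total counts; 180 genes, 125 higher and 55 lower, were called in the same direction under all 4. The count was 493 without untreated mouse 3, 503 without untreated mouse 4 and 544 without untreated mouse 5, and within cluster Neutrophils.3 19 of 667 genes were called. That fit had the same few untreated cells.

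Of 24 hypoxia and glycolysis genes 22 rose (22 adjusted over the list alone), 8 under all 4 scalings, with Ero1l, an oxidoreductase of protein folding (3.28 ± 0.47, adjusted p = 0.000187), and Slc2a1 (2.83). Of 20 tumour-adapted genes 15 rose (15 adjusted over the list alone), 4 under all 4, with Spp1 (2.60 ± 0.40, adjusted p = 0.000295) and Cstb (1.84; -0.12, adjusted p = 0.965 within Neutrophils.3). Both sets were higher (camera adjusted p = 1.27e-26 and 1.87e-15), with adjusted p = 0.0643 and 0.0216 with an estimated correlation. Within Neutrophils.3 both lost their calls, with a median of 0.26 against 2.01 for the hypoxia set and 0.31 against 1.76 for the tumour-adapted set (both adjusted p = 0.192). Of 25 NF-kB and TNF targets 18 rose (20 adjusted over the list alone) but 1, Cxcl2 (2.31 ± 0.41, adjusted p = 0.000821), under all 4. Of 19 stress genes 12 rose (13 adjusted over the list alone), 6 under all 4, with Hspa1a (4.40), Hsp90aa1 (3.19) and Jun (2.65; 0.03, adjusted p = 0.991 within Neutrophils.3). Of 19 class I genes 8 rose (10 adjusted over the list alone), 4 under all 4, with B2m (2.04) and H2-K1 (2.03). Of 23 interferon gamma response genes 7 rose (10 adjusted over the list alone), 3 under all 4, with Cd274 (2.90 ± 0.40, adjusted p = 0.000129) and Socs1 (3.03). Of 10 granule genes 6 rose (7 adjusted over the list alone), 5 under all 4, with Lcn2 (2.96). These sets were higher in camera (adjusted p from 1.37e-12 to 5.49e-06), with adjusted p from 0.0753 to 0.272 with an estimated correlation. Within Neutrophils.3 they kept their calls in camera, with lower medians for the NF-kB (0.67 against 1.67), stress (0.47 against 1.73) and granule sets (2.10 against 4.92). Cxcl2 (0.79, adjusted p = 0.39), Lcn2 (1.67, adjusted p = 0.177) and Socs1 (2.37, adjusted p = 0.232) lost their calls there. Of 22 oxidative phosphorylation genes 3 rose (3 adjusted over the list alone), and Cycs, cytochrome c, did so under all 4 (3.23 ± 0.46, adjusted p = 0.00018). The largest fall, Mvb12b (-2.53 ± 0.55, adjusted p = 0.00399), missed the threshold without untreated mouse 1 (adjusted p = 0.0988). Camera also called adhesion receptors (adjusted p = 2.02e-07; adjusted p = 0.0888 with an estimated correlation; 0.105 within Neutrophils.3), mature circulating neutrophil genes (5.49e-06; adjusted p = 0.232 with an estimated correlation), neutrophil markers (7.79e-05; adjusted p = 0.212 with an estimated correlation) and interferon alpha/beta genes (0.0311; adjusted p = 0.68 with an estimated correlation) higher and macrophage markers lower (0.0327; adjusted p = 0.318 with an estimated correlation). On pooled counts scaled by their totals, the medians of the interferon alpha/beta (-0.46) and mature neutrophil genes (-0.01) were below 0 but above that of all genes (-0.63). The neutrophil markers are a part of the mature neutrophil list here too.

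On the surface, neutrophils of both treated groups held far less CD62L, the selectin that neutrophils shed when activated, than untreated ones. It stood at 128580 ± 17726 antibody CPM (SD, n = 4) in untreated, 2592 ± 1150 (SD, n = 4) in IgG and 2880 ± 1626 (SD, n = 5) in aOX40 mice, the latter values close to the highest isotype control (1948 and 2269 CPM). CD62L fell by 5.64 ± 0.45 (SE) in IgG (adjusted p = 1.12e-06) and by 5.48 ± 0.41 in aOX40 mice (adjusted p = 4.09e-07) on the log2 scale. These folds are fitted values, and no bound was computed. CD62L stood below the mean of the highest isotype control in IgG mice 2 and 5 (1425 and 1834 CPM) and in aOX40 mice 1, 2 and 3 (1736, 1985 and 2230 CPM). The size of the fall is therefore not resolved. The adhesion receptor CD44 (-3.02 and -2.30), the integrin chain CD61 (-2.35 and -1.88), CD24 (-2.81 and -1.65) and CXCR2 (-1.41 and -1.44) also fell. CD11b rose in IgG (1.87 ± 0.20, adjusted p = 6.57e-06) and in aOX40 mice (0.63 ± 0.20, adjusted p = 0.0254; called in 9 of 13 fits with 1 mouse left out, up to 0.0827), and CD169, a sialic acid receptor, in both (0.75 and 0.91). PD-L1 protein was at -0.36 in IgG (adjusted p = 0.566) and -0.45 in aOX40 mice (adjusted p = 0.47), which did not pass the test. Cluster Neutrophils.3 held 56 of 83 untreated neutrophils, but 57 of 1597 IgG and 117 of 3519 aOX40 neutrophils. No protein test was run within a cluster, so a different mix of neutrophils cannot be told apart from a change on the same cells.

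In edgeR 46 of 138 proteins changed in IgG (16 higher, 30 lower) and 39 in aOX40 mice (13 higher, 26 lower). With total count scaling the balance turned, to 92 higher and 12 lower in IgG and 84 higher and 10 lower in aOX40 mice, as the median of all proteins moved from 0.03 to 0.81 and from 0.03 to 0.66. In all, 28 (16 higher, 12 lower) and 23 proteins (13 higher, 10 lower) were called in the same direction by both scalings, all those named above but PD-L1 among them.

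**Figure D3:**
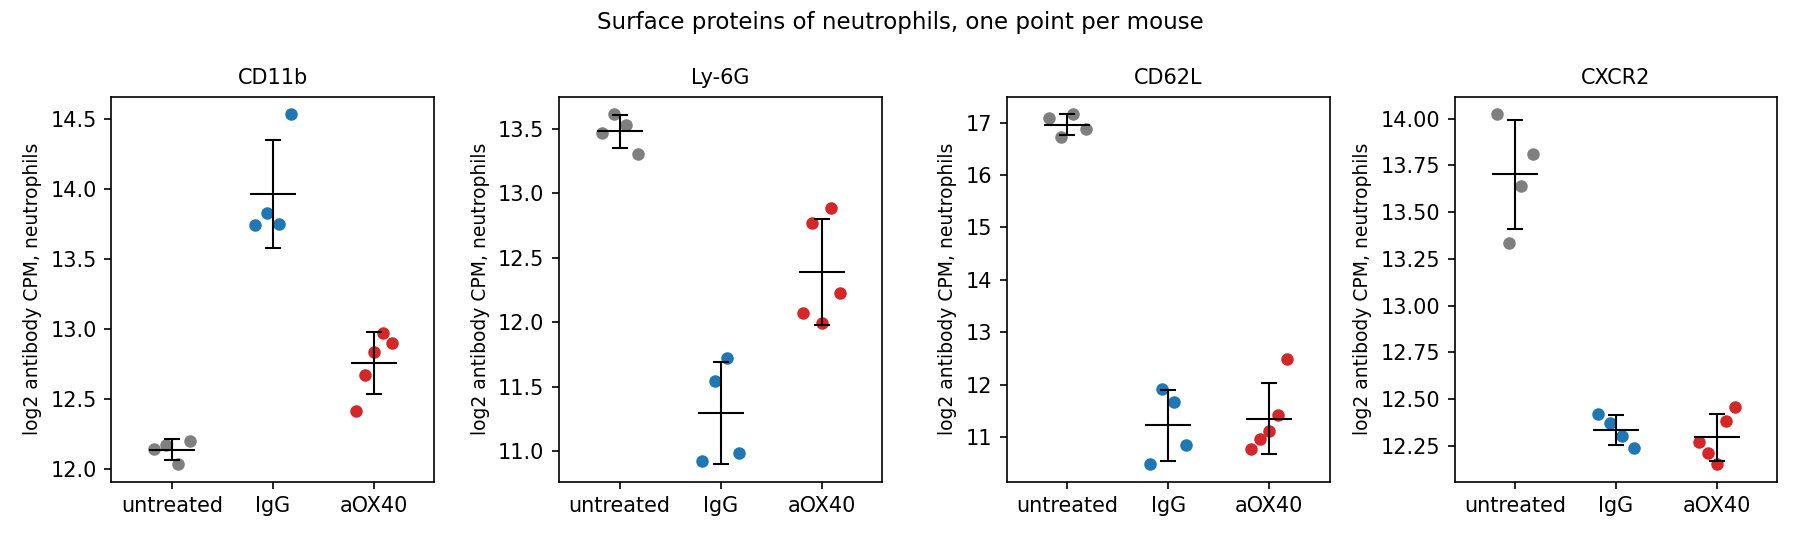
Log2 antibody CPM of 4 surface proteins on neutrophils (points, 1 per mouse; horizontal line and bar, mean and SD of the log2 values), by group; axes do not start at 0. CD62L averaged 128580 CPM in untreated, 2592 in IgG and 2880 in aOX40 mice.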

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

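The tests of a filter on UMIs and of the mix and clusters of neutrophils between aOX40 and IgG mice were chosen after the result was seen. In 60 groups of mice over 22 quantities, 12 values of 7 mice lay far from the others of their group, where chance sets about 1 in 20 groups apart; shares of 1 mouse are not independent. IgG mouse 3 had the lowest share of neutrophils (84.56%; others 97.46% to 99.16%) and the highest shares of cells in clusters named after monocytes or macrophages, called monocytes and macrophages in this section (15.09%; others 0.8432% to 2.542%) and basophils (0.3509%; others 0). It also had the highest median mitochondrial percent in neutrophils (0.5331; others 0.1119 to 0.1201). aOX40 mouse 5 had 17.98% monocytes and macrophages (others 0.5447% to 5.4%) and a median of 882 antibody counts per neutrophil (others 417 to 535). Untreated mouse 1 had 5.556% dendritic cells (others 2.232% to 2.757%) and 92.67% monocytes and macrophages (others 96% to 96.69%). Untreated mouse 5 had a median mitochondrial percent of 0.4195 in its neutrophils (others 0.164 to 0.2097), and untreated mouse 4 0.0806% basophils (others 0). Among neutrophils, Neutrophils.1 made up 1.071% in aOX40 mouse 1 (others 0 to 0.1171%), and Neutrophils.5 34.69% in aOX40 mouse 2 (others 3.864% to 9.636%).

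The first pattern weighed is the share of neutrophils, most cells of both treated libraries and few of the untreated one. A filter that removed cells of many UMIs from the treated libraries is argued against: 480 of 5356 treated cells (205 IgG, 275 aOX40) had more UMIs than the median untreated monocyte or macrophage, 8522.5. A difference in sorting or loading cannot be told apart from the treatment, since each condition was 1 library. The effect of treatment on the tumours stays open beside it.

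The second pattern is the 359 genes that changed between aOX40 and IgG neutrophils. The cells of cluster Neutrophils.1 are argued against as the whole cause: without them the median log2 fold change kept 90.8% of its size for the higher genes (1.19 to 1.08; 109 of 158 tested kept their call) and 86.1% for the lower genes (-1.26 to -1.08; 107 of 184 tested). With the other called genes set to 0 these were 90.3% and 80.9%. A different mix of neutrophil clusters cannot be told apart from a change within clusters. For the lower genes 71.5% of the median was left within Neutrophils.4, but 73 of 200 genes could be tested there. For the higher genes 54.8% was left (132 of 159 genes), between the bounds set for either outcome. An effect of the OX40 antibody stays open beside differences between the 2 libraries.

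The third pattern is the genes that changed against untreated mice in the same direction under 4 scalings. Free RNA of monocytes and macrophages was weighed for the genes higher in untreated mice. The median log2 ratio of their level in untreated monocytes and macrophages to that in untreated neutrophils was -1.75 (quartiles -2.93 and -0.84), with 83 of 91 genes below 0. These genes were picked for high counts in the same untreated neutrophils, which lowers the ratio, so it cannot decide. A different mix of neutrophil clusters cannot be told apart from a change within them. Within Neutrophils.3 the median kept 48.3% of its size for genes higher in treated mice (2.29 to 1.10; 8 of 75 genes kept their call) and 37.5% for lower genes (-1.30 to -0.49; 1 of 57), with few counts per mouse. An effect of treatment stays open beside this mix, beside the library and, for the genes higher in untreated mice, beside free RNA.

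Splits of the mice into groups of the same sizes, the real one counted in, were refitted to weigh chance. Mice of a group shared 1 library, so the splits cannot part an effect of treatment from likeness within a library. Against untreated mice, which also differed in depth, few splits could be expected to match. For genes, 2 of 100 splits called as many as the 359 between aOX40 and IgG mice. Between IgG and untreated mice 1 of 35 called as many as the 728 (highest other 1). Between aOX40 and untreated mice 1 of 100 called as many as the 818 (highest other 542). The split of aOX40 mouse 5 and the 4 IgG mice against the other aOX40 mice called 650 genes, and that of aOX40 mouse 5 with the untreated mice the 542, which points to a structure set by this mouse. For proteins, 2 of 100 splits reached the 6 between aOX40 and IgG mice (highest other 8). Against untreated mice 1 of 35 reached the 46 of IgG mice (highest other 0) and 1 of 100 the 39 of aOX40 mice (highest other 16). For gene lists in camera chance cannot be excluded: 35 of 100 splits called as many as the 9 between aOX40 and IgG mice (highest other 15). Between IgG and untreated mice 3 of 35 called as many as the 12 (highest other 12). Between aOX40 and untreated mice 8 of 100 called as many as the 12 (highest other 14). In each comparison the other splits called a median of 7 lists.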

How the results depend on the processing

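Scaling by total counts, tests within or without clusters, thinning of treated mice alone and leaving out 2 mice were chosen after the data were seen; the cause was not tested for the changes below, save that thinning leaves fewer counts and tests 291 genes. Of the called genes named by the rule, 5 of 39 (aOX40 against IgG), 15 of 71 (IgG against untreated) and 20 of 67 (aOX40 against untreated) kept direction and call in all alternatives, and 14, 45 and 46 with any mouse left out.

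The 359 genes for aOX40 against IgG became 3 with all mice thinned to the smallest total, 162 with treated mice thinned, 80 without Neutrophils.4, 937 without 2 mice, and 150, 41 and 2 within Neutrophils, Neutrophils.4 and Neutrophils.3; leaving out 1 mouse gave 62 to 732. The 728 for IgG against untreated became 423 with RLE size factors, 82 thinned, 470 with total counts and 2 within Neutrophils.3, and 425 to 728 with 1 mouse left out. The 818 for aOX40 against untreated became 424, 103, 513 and 19, and 493 to 884. With an estimated correlation camera called 0 of its 9, 2 of 12 and 1 of 12 lists. In 1 direction fry called 0 for aOX40 against IgG (6 at unadjusted p under 0.05), 13 for IgG against untreated and 12 for aOX40 against untreated. Without regard to direction fry called 9, 15 and 15. With total counts 104 and 94 proteins were called against untreated mice. With 1 mouse left out, which allows fewer permutations, the difference of aOX40 to IgG mice was -23.8 to -15.98 points for Neutrophils and -11.3 to -9.04 for Neutrophils.2.

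Lists whose test changed direction and was called in either fit (medians), aOX40 against IgG: within Neutrophils.3 interferon alpha/beta 0.318, interferon gamma 0.168, class I 0.105, nitric oxide 0.0659 and stress -0.0754; stress -0.372, NF-kB -0.412 and adhesion -0.125 within Neutrophils.4; class II 0.629 and resident macrophage 1.53 within Neutrophils. Against untreated mice: mature neutrophil -0.111 thinned and 0.0155 with total counts, stress 0.255 thinned and oxidative phosphorylation -0.494 within Neutrophils.3 (IgG), and interferon alpha/beta 0.0445 thinned (aOX40). Genes that changed sign and were called in either fit, aOX40 against IgG: Arg1 4.52 and H2-Ab1 0.16 within Neutrophils, Cxcr2 -0.042 within Neutrophils.3, Spp1 -0.68 and Cd69 -0.13 within Neutrophils.4. IgG against untreated: Cxcl10 4.24 without the 5% of cells with the most UMIs and 5.58 without untreated mouse 5 (-1.16 to 5.58 with 1 mouse left out); Ifi47 -0.30, Hmox1 -0.13 and Fcgr3 -0.28 within Neutrophils.3; Mxd1 -0.11, Ccr1 -0.081 and Klf2 -1.15 thinned. aOX40 against untreated: Cxcl10 3.48 and 4.89 in the same settings (-1.78 to 4.89), Cstb -0.12 within Neutrophils.3, Klf2 -1.13 thinned and -1.06 with total counts. As percent of cells other than neutrophils, Monocytes.2 was 68.3 points higher in IgG and 36.6 in aOX40 than in untreated mice (both adjusted p = 0.019), while Monocytes, at 1.21 in aOX40, was not called there (adjusted p = 0.865). These percents rest on as few as 5 cells in a treated mouse.

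Hashtag numbers did not pair mice between aOX40 and IgG (r -0.016, 0.435, -0.028 and -0.061). Alternatives for tests not run, on cell types with too few cells and on shares of the other neutrophil clusters, were not run either. Depth limits the tests against untreated mice, where at most 8% of added 2-fold and 33% of 4-fold changes were called.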

Other observations

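Cluster Monocytes.5, named after monocytes, held 132 cells, all of untreated mice, and was led by the granzyme genes Gzmc (2652 CPM against 0.42 elsewhere) and Gzmb and by Prf1, Thy1 and Cd3g, genes of cytotoxic lymphocytes; 51 of its cells had a T, NK, NKT or ILC label and 55 a monocyte or macrophage label. Monocytes.2, led by Ace (209 CPM against 13.4), Cx3cr1 and Treml4, genes of patrolling monocytes, held 49 IgG, 97 aOX40 and 768 untreated cells. The basophil cluster carried Il4 (1055 CPM against 0), Il6 (825 against 2.69) and Hgf (727 against 3.61). The 11 listed melanocyte genes summed to 21.7 CPM in untreated, 24.6 in IgG and 18.1 in aOX40 neutrophils, and to 30.1 CPM in untreated cells of clusters named after monocytes or macrophages.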
